A study of Mus musculus with 12 samples.

How the data were processed

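RNA was measured in 12 samples of mouse CD4 T cells, 3 from each of 4 sorted cell divisions. Per the labels, naive CD4 T cells of DO11.10 mice, whose T cell receptor recognises an ovalbumin peptide, were stained with the dye CFSE, which is diluted at each division. They were transferred into BALB/c mice that were immunized with the peptide in complete Freund's adjuvant. Lymph node cells were sorted by dye dilution into D3, D4, D6 and D8, which the labels describe as cells that had divided 2, 3, 5 and 7 times. The sample numbers 1 to 3 stand for 3 independent experiments. The labels state total RNA, a biotin labelling kit for Illumina arrays and scanning of bead arrays, and they name no gate on the transferred T cell receptor.

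The authors deposited probe intensity values read out with BeadStudio 2.0, on a linear scale and without normalization between arrays or background subtraction. A detection p-value of each probe, computed by the authors with BeadStudio against the negative controls of the same array, stands beside each intensity in the deposited table, per the file headers. The deposited series matrix holds a second intensity value per probe, which was background-subtracted and brought to nearly the same distribution on all arrays by the authors. Its method was not stated. Its 12 array medians lay between 2.74 and 2.76, and its rank correlation with the first table was 1 on every array. Neither table stated a genome build, and positions are therefore not given.

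The 2 tables held 45281 probes. The annotation table gave 1 symbol for 34885 probes, several for 18 and none for 10378. Current symbols were looked up through gene identifiers for 34807 probes, and 0 symbols differed. Probes with a detection p under 0.05 on at least 3 of the 12 arrays were kept (17829), of which 14972 carried 1 symbol. The brightest probe of each gene over all 12 arrays was tested, which gave 9566 genes. The 2857 detected probes without a single symbol were left out of the gene tests. Among the genes that the rule for named genes took, not all of them named in the text, 108 had more than 1 detected probe. Of these, 18 had a probe of the other sign from D3 to D8, and 0 had a called probe of the other sign. Changes given are those of the brightest probe, and other probes could change much less. From D3 to D8 the 2 probes of Zbtb32 gave 4.23 and 0.70, those of Anxa2 3.70 and 0.68, and those of Bbc3 -2.81 and -0.11. Cd44 and Cd8b1, given as lower, had probes at 0.14 and 0.33.

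Intensities were normalized with neqc of limma 3.58.1 in R 4.3.3 (background correction with negative controls inferred from the detection p, offset 16, quantile normalization, log2). The step of the detection p implied 936 negative controls per array. All 12 arrays entered 1 model with the 4 division means, fitted with lmFit and eBayes of limma (8 residual degrees of freedom), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were the 6 pairs of divisions, D4 against the mean of the other 3 divisions, genes called in all 3 tests of D4 in 1 direction, and a trend with times divided as a numeric term. Changes are given as log2 differences ± standard error, and every division had 3 arrays. A gene not detected on any array of a division has its change between 2 divisions given as a least fold against the detection floor. Values of the trend and of D4 against the mean are given for named genes detected in every division.

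The experiment number was not a term of the model. After the division means were removed, the 18 pairs of arrays from 1 experiment correlated at 0.205 to 0.438, the other 36 pairs at -0.373 to 0.0342, and 12 of 12 arrays correlated best with an array of their own number. Counts with the experiment as a block are given beside the counts that it moved by over 1.5 times.

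Sets of genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over 31 lists within each comparison. The lists covered memory and survival, naive state and quiescence, Th1 and cytotoxic effector genes, follicular helper (Tfh) genes, Th2, Th17 and regulatory genes, early activation, inhibitory receptors, STAT5 and SOCS feedback, pro-apoptotic genes, S phase, G2/M, CDK inhibitors, glycolysis, oxidative phosphorylation, fatty acid oxidation, cholesterol biosynthesis, ribosome biogenesis, ribosomal proteins, dissociation stress, type I interferon, interferon gamma, homing and adhesion, T cell identity, and markers of B cells, plasma cells, CD8 T cells, NK cells, myeloid cells, dendritic cells, erythroid cells and stroma. Members that passed were counted over all genes tested and adjusted over the list alone. All camera calls reported were lost with an estimated correlation, whose p is given beside each. That correlation was estimated without the experiment as a block, although arrays of the same experiment correlated after the division means were removed. Genes of a list that vary together between experiments can raise it. Whether the calls would also be lost with the block was not tested.

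The comparisons, tests, filters, lists and listed alternatives were fixed before the data were examined, as was the rule for named genes. That rule took, for each comparison, the 10 called genes with the largest change in each direction and the same sign in all 3 experiments, the 4 members of each list with the smallest p, and a set of T cell genes. Every gene named as changed in a pair of divisions or against the mean had the same sign in 3 of 3 experiments. Genes named outside the rule are stated to be so.

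Arrays were simulated from the mean of each gene, normal noise with its spread in the fit with the experiment block, and reduced experiment effects. The noise was independent between genes, and real arrays may depart from it. The model was tested on changes added to 200 genes of these simulated arrays. For D4 against D3 it recovered 52.2% of 1.5-fold changes, 91.0% of 2-fold changes and 100% of 4-fold changes. For a gene apart at D4 from all 3 others, the values were 43.3%, 88.1% and 100%. With so many genes changed, the simulated D4 against D3 called 165 genes, where the real one called 1. The Benjamini-Hochberg threshold is stricter where fewer genes change. These shares can therefore overstate what the model finds when few genes differ at D4. The alternatives were other background corrections (normexp with offset 50, or none), median centring in place of quantile normalization, the authors' series matrix values floored at 16, no detection filter, a stricter filter (p under 0.01), all probes, array weights, eBayes with trend and robust, the experiment block, only the 2 divisions compared, and each array left out in turn. The depth of an array is its signal over background. Between 15563 and 16666 probes were detected per array, and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.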

Results

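Gene expression was measured on Illumina bead arrays in mouse CD4 T cells sorted 3 days after immunization by how often they had divided. D3, D4, D6 and D8 each had 3 arrays from 3 independent experiments. Per the design text, D4 cells readily gave memory cells after transfer and D3, D6 and D8 cells did so less. The comparisons therefore ask which genes set D4 apart, and which follow the number of divisions. Detected probes averaged 16316 ± 241 (SD, n = 3) in D3, 16194 ± 453 in D4, 16317 ± 303 in D6 and 15898 ± 297 in D8. Median intensity lay between 41.6 and 51.2 on the 12 arrays. Cd4 had a log2 intensity of 8.13 ± 0.10 (SD, n = 3) in D3 and 8.22 ± 0.10 in D8, and Cd3e, a chain of the T cell receptor complex, had 13.25 ± 0.12 and 13.07 ± 0.07.

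The arrays followed the order of division. The first principal component held 61.8% of the variance, with scores of -24.2 ± 2.06 (SD, n = 3) in D3, -15.6 ± 0.750 in D4, 6.95 ± 1.08 in D6 and 32.9 ± 5.91 in D8. Of the 3492 genes called between D8 and D3, 2465 (70.6%) had their 4 means in the order of division, which a choice of genes by their D8 minus D3 difference favours, and of all genes 35.4% had.

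**Figure D1:**
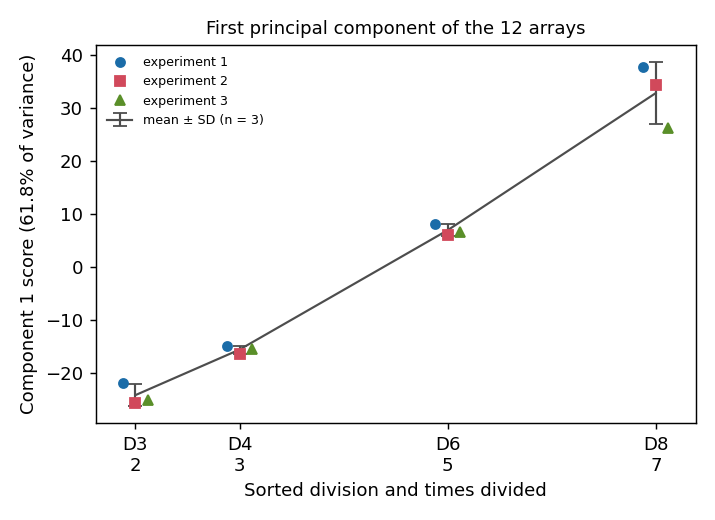
First principal component score of each of the 12 arrays (points, coloured by experiment) against sorted division and times divided, with the mean and SD of each division (n = 3). Scores rise from D3 (mean -24.2) through D4 (-15.6) and D6 (6.95) to D8 (32.9).

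D8 was compared with D4 to ask what differs between much divided effectors of reduced memory potential and the division that readily gave memory. S100a6, a calcium-binding protein, rose by 3.80 ± 0.22 log2 units, Anxa2, a membrane-binding annexin, by 3.53 ± 0.25, Lgals3, a galectin, by 3.40 ± 0.30, and Cxcr3, a chemokine receptor of Th1 cells, by 3.31 ± 0.29. Emp1 (3.56 ± 0.14), Chil5 (3.49 ± 0.15), the transcriptional repressor Zbtb32 (3.46 ± 0.19), the interferon-induced Ifitm3 (3.31 ± 0.28) and Plac8 (3.17 ± 0.56) also rose, and Popdc2, not detected in D4, was at least 7.55-fold higher. Sapcd1 fell by 4.11 ± 0.23, the phospholipase Pla2g4f by 4.07 ± 0.32, Wnt10a by 3.13 ± 0.24, Nrn1 by 3.07 ± 0.19, Tmie by 3.03 ± 0.21, Cd86, a costimulatory ligand, by 2.89 ± 0.18, and Pik3r3, a regulatory subunit of PI3 kinase, by 2.70 ± 0.17. Adjusted p for these genes was at most 0.000778.

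All 25 measured G2/M genes rose (25 adjusted over the list alone), with a median of 1.72, and 25 of 29 S phase genes rose (27 adjusted over the list alone), with a median of 0.95. Examples were Cdc25b, a phosphatase that starts mitosis (2.61 ± 0.15), Kif11, a spindle motor (1.76 ± 0.13), Rrm2, a subunit of ribonucleotide reductase (1.92 ± 0.25), and Cdc45, a replication fork protein (1.27 ± 0.16). Camera gave an adjusted p of 1.09e-23 for G2/M and 3.29e-14 for S phase, and with an estimated correlation the adjusted p was 0.189 and 0.269. Of 17 CDK inhibitors and cell cycle exit genes, 6 rose and 3 fell, the same counts as adjusted over the list alone. Cdkn2c, an inhibitor of CDK4 and CDK6, rose by 1.96 ± 0.13, and Mxd4, an antagonist of MYC, fell by 1.22 ± 0.13.

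Cholesterol biosynthesis had 10 of 17 members higher (12 adjusted over the list alone), such as Mvk, mevalonate kinase, by 1.36 ± 0.16, and Fdps, farnesyl diphosphate synthase, by 1.03 ± 0.17, with a camera adjusted p of 1.26e-05 and an adjusted p of 0.255 with an estimated correlation. Glycolysis had 8 of 17 genes higher and 1 lower (10 and 1 adjusted over the list alone), with Pgk1 at 1.07 ± 0.12 and Tpi1 at 1.12 ± 0.14, while Pfkm, a phosphofructokinase subunit, fell by 0.84 ± 0.09. Its camera adjusted p was 0.00706, and the adjusted p with an estimated correlation was 0.261. Oxidative phosphorylation had 10 of 34 genes higher and 1 lower (10 and 1 adjusted over the list alone), with a median of 0.22, a camera adjusted p of 0.00460 and an adjusted p of 0.325 with an estimated correlation. Fatty acid oxidation had 0 higher and 2 lower of 18, ribosome biogenesis 1 higher and 4 lower of 27 (0 and 4 adjusted over the list alone), cytosolic ribosomal proteins 1 higher and 6 lower of 27, and dissociation stress 1 higher of 14 (0 adjusted over the list alone), and camera called none of these 4 lists.

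Of 24 naive state genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone). Ccr7, the receptor that keeps T cells in lymph nodes, fell by 1.48 ± 0.20, Foxp1 by 1.26 ± 0.14 and Pik3ip1, an inhibitor of PI3 kinase, by 2.01 ± 0.26, whereas Klf2, a factor of quiescence and lymph node exit, rose by 1.61 ± 0.13. Of 25 early activation genes, 11 fell and 1 rose (13 and 3 adjusted over the list alone). Cd69 fell by 1.49 ± 0.15, the phosphatases Dusp2 and Dusp6 by 1.29 ± 0.11 and 1.34 ± 0.12, Cd83 by 1.66 ± 0.15 and Il2 by 1.05 ± 0.22. Camera adjusted p was 0.00307 for the naive list and 0.000324 for early activation, and the adjusted p with an estimated correlation was 0.255 and 0.189.

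Survival genes went both ways. In the memory and survival list 4 of 17 genes rose and 4 fell, the same counts as adjusted over the list alone, and its median (-0.05) and mean (0.28) differed in sign with a camera adjusted p of 0.925. Bcl2, which blocks apoptosis, fell by 1.22 ± 0.12, Socs3, an inhibitor of cytokine signals, rose by 2.43 ± 0.24, and Il7r, the receptor of a survival cytokine, had a change of 0.33 ± 0.30 that did not pass (adjusted p 0.45). In the pro-apoptotic list 5 of 22 genes rose and 3 fell (6 and 5 adjusted over the list alone). The BH3-only genes Bbc3 and Bcl2l11 fell by 2.12 ± 0.16 and 1.42 ± 0.16, and Bmf, not detected in D8, was at least 1.90-fold lower.

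Il21 was at least 6.78-fold higher, Il4 at least 5.77-fold, Il17f at least 4.17-fold and Il10 at least 2.14-fold, none of them detected in D4, and Ifng, the main Th1 cytokine, rose by 1.37 ± 0.20, whereas Lta, a cytokine of the TNF family, fell by 1.32 ± 0.16. The Th1 list had 6 genes higher and 4 lower of 18 (9 and 4 adjusted over the list alone), the Tfh list 4 and 3 of 13 (5 and 3), with Cxcr5 at 1.88 ± 0.15, and the list of Th2, Th17 and regulatory genes 5 and 2 of 14 (5 and 3). Camera called none of these 3 lists. Tbx21, the Th1 master factor, had a change of 0.53 ± 0.19 and an adjusted p of 0.052, which was 0.023 with the experiment block. Bcl6, the Tfh factor, had 0.48 ± 0.22 with an adjusted p of 0.12, which was 0.025 with the block. Inhibitory receptors had 2 of 7 higher and 4 lower (the same adjusted over the list alone), with a median of -0.47, a mean of 0.14 and a camera adjusted p of 0.721. Tigit rose by 2.35 ± 0.24, Havcr2, not detected in D4, was at least 1.91-fold higher, and Tox fell by 0.99 ± 0.14. STAT5 and SOCS feedback had 4 of 10 higher and 2 lower (the same adjusted over the list alone): the cytokine gene Lif rose by 1.22 ± 0.27, and the survival kinase gene Pim2 fell by 0.84 ± 0.19.

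Genes induced by interferon gamma and homing genes were also split, whereas the type I interferon genes that passed all rose. Of 24 type I interferon genes, 9 rose and 0 fell (11 and 0 adjusted over the list alone), among them Oas3 (1.61 ± 0.13) and Oas2 (2.24 ± 0.37), with a camera adjusted p of 0.000324 and an adjusted p of 0.590 with an estimated correlation. Of 15 genes induced by interferon gamma, 2 rose and 4 fell (the same adjusted over the list alone), with Gbp2 and Irf1 lower by 0.92 ± 0.15 and 0.62 ± 0.11. Of 24 homing genes, 8 rose and 6 fell (8 and 7 adjusted over the list alone): Cxcr4 rose by 2.57 ± 0.30 and Gpr183 by 1.57 ± 0.20, and Cd44 fell by 1.02 ± 0.12 and Ccr8 by 1.49 ± 0.20.

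Markers of other cells did not move together. T cell identity had 0 of 19 genes higher and 3 lower (0 and 2 adjusted over the list alone). In the B cell list 2 of 10 rose and 2 fell: H2-Ab1, a class II chain, rose by 1.04 ± 0.20, and Cd72 and H2-DMb2 fell by 1.66 ± 0.27 and 0.85 ± 0.14. The plasma cell list had 1 of 4 higher and 1 lower, Xbp1 (0.67 ± 0.13) and Derl3, which was not detected in D8 and at least 1.65-fold lower, and the myeloid list 1 and 1 of 8. Cd86 was the 1 gene of 6 in the dendritic cell list that passed. The NK gene Klrd1, the 1 member measured, rose by 1.23 ± 0.25. Cd8b1 had a change of -0.30 ± 0.15 with an adjusted p of 0.16, which was 0.027 with the block, and 0 of 2 erythroid and 0 of 3 stromal genes passed. Lyz2 (0.97 ± 0.39, adjusted p 0.075) and Pecam1 (-0.25 ± 0.17, 0.29) passed only with the block (0.040 and 0.047). With the block, the Th1 list had 10 genes higher, ribosome biogenesis 7 lower, ribosomal proteins 3 higher, early activation, dissociation stress and the myeloid list 2 higher each, glycolysis 2 lower, fatty acid oxidation and T cell identity 1 higher each, and type I interferon and stroma 1 lower each. In all, 1327 genes were higher and 1401 lower in D8 (2728 of 9566), 530 of them by over 2-fold. With median centring the count was 1594 (819 higher, 775 lower), and with every probe tested it was 4271 probes.

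**Figure D2:**
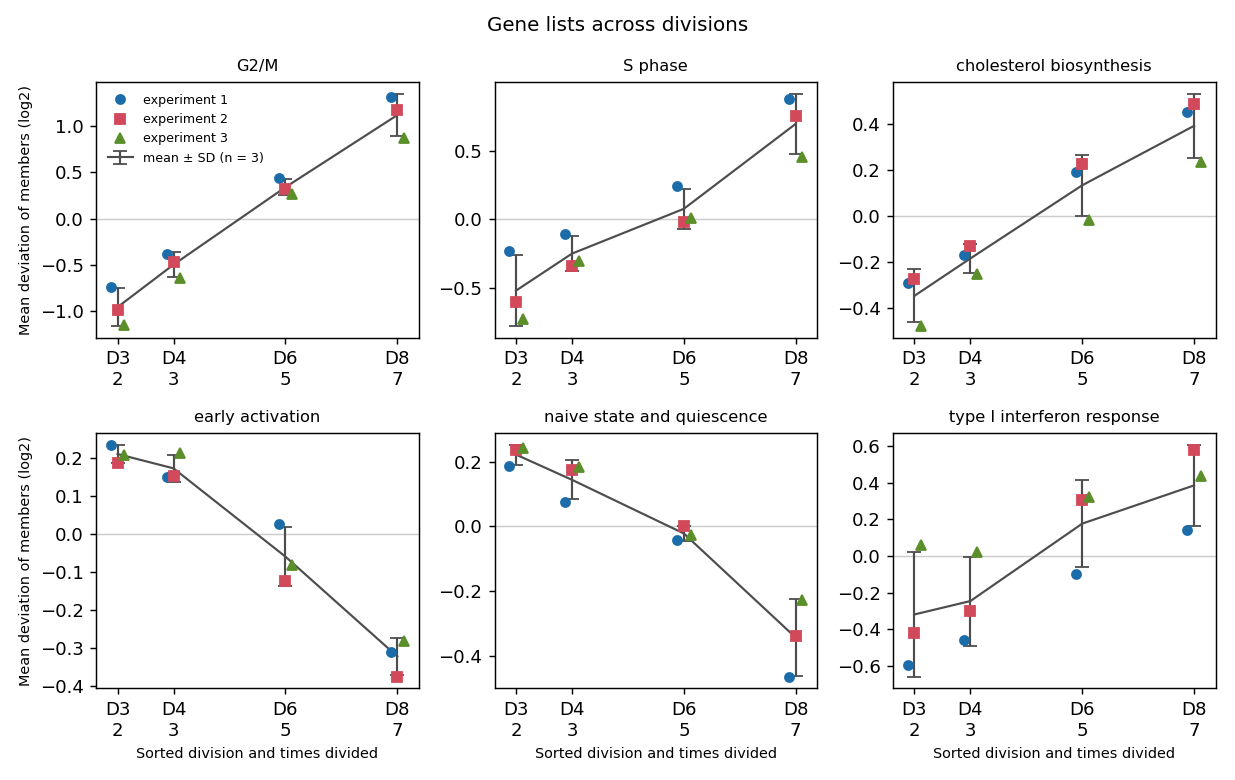
Mean deviation of the measured members of 6 gene lists from their mean over all arrays (log2) on each array, against sorted division and times divided. Points are arrays, coloured by experiment, and lines join the means with SD (n = 3).

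D6 was compared with D4 to ask which of these differences were present 2 divisions after D4. Zbtb32 and Chil5 had each risen by 2.35 (± 0.19 and ± 0.15), Emp1 by 2.16 ± 0.14, the tubulin gene Tubb2b by 2.14 ± 0.23, Cxcr3 by 2.07 ± 0.29, Socs3 by 1.80 ± 0.24 and the kinase gene Sgk1 by 1.59 ± 0.19. Arhgap20 fell by 2.08 ± 0.23, Sapcd1 by 1.91 ± 0.23, Sp6 by 1.81 ± 0.24, Sytl2, a factor of vesicle transport, by 1.69 ± 0.22, Nrn1 by 1.58 ± 0.19, Igsf3 by 1.54 ± 0.19 and Wnt10a by 1.49 ± 0.24. Adjusted p for these genes was at most 0.00272.

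Mitotic genes led the lists. Of 25 G2/M genes, 20 rose (24 adjusted over the list alone), with Cdc25b at 1.39 ± 0.15, Ckap2 at 0.99 ± 0.12, Kif22 at 1.03 ± 0.14 and Nusap1 at 0.98 ± 0.13, a camera adjusted p of 1.16e-27 and an adjusted p of 0.156 with an estimated correlation. S phase had 0 of 29 genes past the threshold (0 adjusted over the list alone, 10 with the block), a median of 0.30, a camera adjusted p of 2.04e-06 and an adjusted p of 0.403 with an estimated correlation. Early activation had 5 of 25 genes lower and 1 higher (the same adjusted over the list alone), with Cd69 lower by 0.81 ± 0.15, Dusp2 by 0.67 ± 0.11 and Tnfrsf9, a costimulatory receptor, by 0.71 ± 0.13. Camera gave an adjusted p of 0.000807, and the adjusted p was 0.156 with an estimated correlation. Of 22 pro-apoptotic genes, 0 rose and 3 fell (1 and 3 adjusted over the list alone): Bbc3 by 1.23 ± 0.16, Bcl2l11 by 1.02 ± 0.16, and Bmf, at least 1.95-fold lower and not detected in D6.

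Cholesterol biosynthesis had 3 of 17 genes higher (3 adjusted over the list alone), with Mvk at 1.02 ± 0.16, a camera adjusted p of 1.90e-05 and an adjusted p of 0.229 with an estimated correlation. The type I interferon list had 3 of 24 higher (6 adjusted over the list alone), with Oas3 at 0.74 ± 0.13, a camera adjusted p of 1.76e-05 and an adjusted p of 0.403 with an estimated correlation. A further 3 lists had camera calls that were lost with an estimated correlation: Tfh (4 of 13 higher, adjusted p 0.0423 and then 0.204), CDK inhibitors (3 of 17 higher, 0.0452 and then 0.204) and ribosome biogenesis (0 of 27 passed, median -0.20, 0.00143 and then 0.403). With the block, ribosome biogenesis had 2 genes lower, type I interferon 9 higher and the pro-apoptotic list 1 higher. Cdkn2c and Cdkn2d, 2 of the CDK inhibitors, rose by 0.93 ± 0.13 and 0.90 ± 0.14. Klf2 rose by 1.07 ± 0.13, Gpr183 by 1.33 ± 0.20, S100a6 by 1.39 ± 0.22 and Lgals1 by 1.06 ± 0.18, and Atp1b1 fell by 1.16 ± 0.16. Bcl2 had a change of -0.37 ± 0.12 that did not pass (adjusted p 0.11, and 0.023 with the block), and Il7r one of 0.27 ± 0.30 (adjusted p 0.72). Of the other-cell markers, Cd86 fell by 1.25 ± 0.18 and Derl3 by 0.67 ± 0.12, and Klrd1 rose by 0.98 ± 0.25 (adjusted p 0.044, and 0.00016 with the block). Cd22 (0.97 ± 0.31, adjusted p 0.106) and Cd72 (-0.70 ± 0.27, 0.181) passed only with the block (0.036 and 0.040). The call of Klrd1 was lost, with adjusted p from 0.052 to 0.17, without each of D3 replicates 2 and 3, D4 replicates 1, 2 and 3, D6 replicates 2 and 3 and D8 replicate 3.

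In D6, 224 genes were higher and 184 lower than in D4 (408 in all, 81 by over 2-fold), and 949 with the experiment block. The count was 162 with median centring (70 higher, 92 lower), and 253, 263, 247, 252 and 215 without D4 replicate 1, D4 replicate 2, D6 replicate 1, D6 replicate 2 and D6 replicate 3.

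D4 was compared with D3 to ask what separates neighbouring divisions of high and reduced memory potential. They were close to each other. Fibcd1, a receptor for acetylated sugars, was the 1 gene called, lower in D4 by 0.78 ± 0.10 (adjusted p 0.024, lower in 3 of 3 experiments). Its means were 6.45 in D3, 5.67 in D4, 4.68 in D6 and 4.40 in D8. Of 25 G2/M genes, 0 passed over all genes (13 rose with the block) and 18 rose when adjusted over the list alone, with a median of 0.51, a camera adjusted p of 1.15e-21 and an adjusted p of 0.311 with an estimated correlation. S phase (median 0.26), oxidative phosphorylation (0.10) and cholesterol biosynthesis (0.19) had no member past the threshold over all genes or adjusted over the list alone, except 1 S phase gene with the block. Their camera adjusted p was 1.25e-08, 1.56e-05 and 0.00195, and the adjusted p with an estimated correlation was 0.751, 0.311 and 0.751.

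With the experiment block, 49 genes were higher and 16 lower (65 in all). Fibcd1 was among them (adjusted p 0.0098 with the block). The other named ones had these changes, of which none passed without the block: Kif22 0.67 ± 0.14 (adjusted p 0.018 with the block, 0.185 without), Nusap1 0.62 ± 0.13 (0.022 and 0.185), Ckap2 0.54 ± 0.12 (0.034 and 0.194), Cdca8 0.65 ± 0.14 (0.028 and 0.205), Cdkn2c 0.61 ± 0.13 (0.048 and 0.185), Cdkn3 0.77 ± 0.24 (0.018 and 0.46), Nrp1 0.70 ± 0.23 (0.018 and 0.48), Gcnt1 0.71 ± 0.15 (0.035 and 0.185), Bmf -0.62 ± 0.11 (0.018 and 0.10) and Bbc3 -0.69 ± 0.16 (0.031 and 0.22). Cxcr3 (0.76 ± 0.29, adjusted p 0.55), Ccr7 (-0.29 ± 0.20), Bcl2 (-0.04 ± 0.12), Il7r (-0.02 ± 0.30) and Ifng (0.13 ± 0.20) did not pass with or without it. At an unadjusted p under 0.05, limma gave 656 genes. The count was 0 without each of 10 arrays (D3 replicates 1, 2 and 3, D4 replicates 2 and 3, D6 replicates 1, 2 and 3, D8 replicates 1 and 2), 2 without D4 replicate 1 and 1 without D8 replicate 3, and Fibcd1 was lost without 11 of the 12 arrays. It was 9 with the authors' values (4 higher, 5 lower).

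D4 was also compared with the mean of D3, D6 and D8, since D4 alone readily gave memory. Sapcd1 was higher in D4 by 1.91 ± 0.19, Pla2g4f by 1.71 ± 0.26, Nrn1 by 1.47 ± 0.15, Wnt10a by 1.42 ± 0.20, Tmie by 1.30 ± 0.17, Cd86 by 1.29 ± 0.14 and Apol9a by 1.28 ± 0.12. Lower in D4 were Emp1 (-1.68 ± 0.12), Zbtb32 (-1.68 ± 0.15), Anxa2 (-1.67 ± 0.20), Ifitm3 (-1.55 ± 0.23), Cxcr3 (-1.54 ± 0.23), Rnase4 (-1.53 ± 0.12) and Socs3 (-1.36 ± 0.19). Adjusted p for these 14 genes was at most 0.00175. Many of these genes did not have D4 as their extreme. Sapcd1 had means of 10.71 in D3, 10.42 in D4, 8.51 in D6 and 6.31 in D8, and Cxcr3 5.37, 6.13, 8.20 and 9.44. Emp1, Zbtb32, Anxa2, Pla2g4f, Wnt10a, Tmie, Nrn1 and Cd86 also had their D4 mean between those of D3 and D8.

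Of 25 G2/M genes, 21 were lower in D4 (24 adjusted over the list alone), with Cdc25b at -1.19 ± 0.12, a camera adjusted p of 7.86e-25 and an adjusted p of 0.168 with an estimated correlation. S phase had 0 of 29 past the threshold and 18 lower adjusted over the list alone, with a camera adjusted p of 5.77e-09 and an adjusted p of 0.425 with an estimated correlation. Early activation had 6 of 25 genes higher in D4 (7 adjusted over the list alone), with Cd83 at 0.68 ± 0.13, a camera adjusted p of 0.000143 and an adjusted p of 0.168 with an estimated correlation. Cholesterol biosynthesis had 2 of 17 lower and type I interferon 4 of 24 lower (6 and 5 adjusted over the list alone), each with a camera adjusted p of 0.000143 and, with an estimated correlation, an adjusted p of 0.320 and 0.637. The naive list (3 of 24 higher, 1 lower) and glycolysis (3 of 17 lower, 1 higher) each had a camera adjusted p of 0.0196 and an adjusted p of 0.320 with an estimated correlation. With the block, 18 S phase genes, 6 of cholesterol biosynthesis, 8 of type I interferon and 6 of glycolysis were lower and 7 naive genes higher. Bbc3 was higher in D4 by 0.89 ± 0.13, Klf2 was lower (-0.86 ± 0.10), and Il7r had a difference of -0.21 ± 0.24 that did not pass (adjusted p 0.72). Of the other-cell markers, Cd86 and Derl3 passed. Klrd1 (-0.69 ± 0.21, adjusted p 0.069), Cd72 (0.62 ± 0.22, 0.13), H2-DMb2 (0.37 ± 0.11, 0.074) and Xbp1 (-0.27 ± 0.11, 0.175) passed only with the block (0.00045, 0.023, 0.031 and 0.035).

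In this comparison 277 genes were higher and 289 lower in D4 (566 in all, 56 by over 2-fold), and 1209 with the experiment block. All 566 were also called between D8 and D4 in the opposite sense, and 0 between D4 and D3 in the same sense. The comparison therefore does not single out genes particular to D4. D4 had the highest or lowest of the 4 means in 183 of the 566 (32.3%), against 32.6% of all genes. The count was 226 with median centring (107 higher, 119 lower), and 327, 281 and 339 without D4 replicates 1, 2 and 3. A gene tied to D4 would differ from each other division in 1 direction: limma called 0 such genes, 21 at an unadjusted p under 0.05, and 0 and 47 with the block.

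D8 was compared with D3 as the last and the first division sampled. Emp1 rose by 4.25 ± 0.14, Zbtb32 by 4.23 ± 0.19, Cxcr3 by 4.07 ± 0.29, Anxa2 by 3.70 ± 0.25, Lgals3 by 3.40 ± 0.30, Plac8 by 3.40 ± 0.56 and the potassium channel gene Kcnk5 by 3.25 ± 0.24. S100a6 and Chil5, not detected in D3, were at least 12.5-fold and 10.3-fold higher. Pla2g4f and Sapcd1 each fell by 4.40 (± 0.32 and ± 0.23), Tmie by 3.50 ± 0.21, Wnt10a by 3.47 ± 0.24, Nrn1 by 3.32 ± 0.19, Cd86 by 3.18 ± 0.18 and the transcription factor Sox4 by 3.03 ± 0.24. Adjusted p for these genes was at most 0.000308.

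All 25 G2/M genes rose (25 adjusted over the list alone), with a median of 2.28, and 28 of 29 S phase genes (29 adjusted over the list alone), with a median of 1.14. Cdc25b rose by 3.03 ± 0.15, Kif22 by 2.55 ± 0.14, Rrm2 by 2.57 ± 0.25 and Tk1, a thymidine kinase, by 2.06 ± 0.22. Camera adjusted p was 1.18e-23 and 1.97e-15, and the adjusted p with an estimated correlation was 0.189 and 0.232. Cholesterol biosynthesis had 12 of 17 higher (15 adjusted over the list alone), oxidative phosphorylation 15 of 34 higher and 1 lower (17 and 1) and glycolysis 9 of 17 higher and 2 lower (10 and 2). Their camera adjusted p was 1.98e-06, 3.08e-05 and 0.0113, and with an estimated correlation the adjusted p was 0.190, 0.190 and 0.232. Of 24 type I interferon genes, 12 rose and 1 fell (the same adjusted over the list alone), with a camera adjusted p of 0.000328 and an adjusted p of 0.631 with an estimated correlation.

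Of 25 early activation genes, 14 fell and 1 rose (14 and 2 adjusted over the list alone), and of 24 naive genes 10 fell and 1 rose (12 and 1). With the block 3 early activation genes rose and 2 type I interferon genes fell. Cd69 fell by 1.83 ± 0.15, Dusp2 by 1.55 ± 0.11, Ccr7 by 1.77 ± 0.20 and Pik3ip1 by 2.31 ± 0.26. Camera adjusted p was 0.000639 and 0.00223, and the adjusted p with an estimated correlation was 0.189 and 0.190. Bbc3 fell by 2.81 ± 0.16, Bcl2l11 by 1.91 ± 0.16 and Bcl2 by 1.27 ± 0.12, while Il7r had a change of 0.32 ± 0.30 (adjusted p 0.44). Of the other-cell markers, Cd72 fell by 2.15 ± 0.27, H2-DMb2 by 0.68 ± 0.14 and Ctss by 0.81 ± 0.18, and H2-Ab1 rose by 1.30 ± 0.20, Klrd1 by 1.37 ± 0.25 and Xbp1 by 0.79 ± 0.13. Cd22, not detected in D3, was at least 3.01-fold higher, and Derl3, not detected in D8, at least 1.72-fold lower. Cd8b1 (-0.36 ± 0.15, adjusted p 0.075), Hbb-bt (-0.96 ± 0.57, 0.21) and Pecam1 (-0.35 ± 0.17, 0.118) passed only with the block (0.0077, 0.031 and 0.0075). In all 1682 genes were higher and 1810 lower in D8 (3492), 728 by over 2-fold. Median centring gave 2396 genes, 881 higher and 1515 lower, and every probe tested gave 5740 probes.

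D6 was compared with D3, both of reduced memory potential and on either side of D4. Zbtb32 rose by 3.12 ± 0.19, Emp1 by 2.85 ± 0.14, Cxcr3 by 2.83 ± 0.29, Tubb2b by 2.51 ± 0.23 and Cdkn3 by 2.10 ± 0.24. Arhgap20 fell by 3.00 ± 0.23, Sytl2 by 2.37 ± 0.22, Igsf3 by 2.30 ± 0.19 and Bbc3 by 1.92 ± 0.16. Of 25 G2/M genes 23 rose (24 adjusted over the list alone), and of 29 S phase genes 17 (20), with camera adjusted p of 1.21e-28 and 7.55e-11 and, with an estimated correlation, adjusted p of 0.179 and 0.284. Cholesterol biosynthesis (8 of 17 higher), oxidative phosphorylation (3 of 34 higher), type I interferon (6 of 24 higher) and Tfh (5 of 13 higher) had camera adjusted p of 1.32e-06, 0.000569, 6.07e-05 and 0.0264. With an estimated correlation the adjusted p was 0.179, 0.240, 0.461 and 0.179. Early activation (6 of 25 lower, 1 higher) and ribosome biogenesis (1 of 27 lower) had camera adjusted p of 0.00328 and 0.0246, and with an estimated correlation the adjusted p was 0.179 and 0.570. With the block, 6 oxidative phosphorylation and 12 type I interferon genes were higher, and 4 ribosome biogenesis genes and 1 type I interferon gene lower. Cd69 fell by 1.14 ± 0.15, Klf2 rose by 1.17 ± 0.13, and of the other-cell markers Cd86, Cd72 and Derl3 fell by 1.54 ± 0.18, 1.19 ± 0.27 and 0.74 ± 0.12. Klrd1 rose by 1.12 ± 0.25, Cd22, not detected in D3, was at least 2.64-fold higher, and H2-Ab1 rose by 0.78 ± 0.20 (adjusted p 0.018). The adjusted p of H2-Ab1 was 0.062, 0.061, 0.074 and 0.055 without D3 replicate 1, D3 replicate 2, D6 replicate 1 and D6 replicate 3. Xbp1 (0.39 ± 0.13, adjusted p 0.069) and Ctss (-0.39 ± 0.18, 0.177) passed only with the block (0.011 and 0.022).

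In D6, 708 genes were higher and 711 lower than in D3 (1419 in all, 225 by over 2-fold), and 2214 with the block. Median centring, which put the median change of all genes at -0.135, gave 230 higher and 700 lower (930), and the count was 938 without D6 replicate 2 and 2162 with every probe tested.

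D8 was compared with D6 to ask what changed over the last divisions sampled. Lgals3 rose by 2.76 ± 0.30, S100a6 by 2.41 ± 0.22, Socs2 by 2.09 ± 0.22, Ifitm3 by 2.06 ± 0.28, Cxcr4 by 2.01 ± 0.30, Myo1f, a motor protein of leukocytes, by 1.98 ± 0.16, Tigit by 1.95 ± 0.24, Sema7a by 1.92 ± 0.15 and Il4 by 1.85 ± 0.20. Ifng, not detected in D6, was at least 2.76-fold higher. Pla2g4f fell by 2.70 ± 0.32, Pik3r3 by 1.84 ± 0.17, Cd86 by 1.64 ± 0.18, Igfbp4 by 1.53 ± 0.26, Cd83 by 1.36 ± 0.15, Ccr7 by 1.23 ± 0.20, the inhibitory receptor Lag3 by 1.04 ± 0.14 and Bcl2 by 0.85 ± 0.12.

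Of 29 S phase genes 18 rose (26 adjusted over the list alone), with Cdc45 at 0.84 ± 0.16, and of 25 G2/M genes 22 rose (24), with Top2a at 0.97 ± 0.14. Camera adjusted p was 3.47e-15 and 8.31e-20, and the adjusted p with an estimated correlation was 0.297 and 0.288. The Th1 list (5 of 18 higher, 2 lower), glycolysis (3 of 17 higher, 1 lower), oxidative phosphorylation (2 of 34 higher) and cholesterol biosynthesis (3 of 17 higher) had camera adjusted p of 0.0180, 0.0164, 0.00577 and 0.00577, and with an estimated correlation the adjusted p was 0.297, 0.297, 0.361 and 0.373. Early activation (7 of 25 lower), the naive list (6 of 24 lower, 1 higher), ribosomal proteins (1 of 27 lower) and T cell identity (2 of 19 lower) had camera adjusted p of 0.00314, 0.00586, 0.00771 and 0.0415, and with an estimated correlation the adjusted p was 0.288, 0.297, 0.373 and 0.414. With the block, oxidative phosphorylation and cholesterol biosynthesis each had 6 higher, early activation 11 lower and 3 higher, the naive list 10 lower, the Th1 list 4 lower and ribosomal proteins 3 lower. Of the other-cell markers besides Cd86, H2-DMb2 fell by 0.78 ± 0.14, Cd72 by 0.96 ± 0.27 (adjusted p 0.039), and Derl3, not detected in D8, was at least 1.03-fold lower (adjusted p 0.039). Without each of D6 replicates 1 and 2 and D8 replicates 1, 2 and 3 the calls of Cd72 (adjusted p 0.081 to 0.15) and Derl3 (0.067 to 0.14) were lost. Xbp1 (0.41 ± 0.13, adjusted p 0.074), Ctss (-0.41 ± 0.18, 0.187) and Cst3 (0.31 ± 0.12, 0.12) passed only with the block (0.010, 0.022 and 0.034). In D8, 457 genes were higher and 434 lower than in D6 (891 in all, 129 by over 2-fold), and 1662 with the block. The count was 338 with median centring (190 higher, 148 lower), and 507, 547, 370 and 531 without D6 replicate 2, D6 replicate 3, D8 replicate 1 and D8 replicate 2.

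A trend with times divided was fitted to ask which genes followed division across all 12 arrays. Emp1 and Zbtb32 rose by 0.88 log2 units per division (± 0.03 and ± 0.05), Cxcr3 by 0.84 ± 0.05, Anxa2 by 0.77 ± 0.05, Tubb2b by 0.68 ± 0.06 and Kcnk5 by 0.67 ± 0.04. Sapcd1 fell by 0.91 ± 0.05 per division, Pla2g4f by 0.88 ± 0.08, Wnt10a by 0.71 ± 0.05, Tmie by 0.70 ± 0.04, Bbc3 by 0.56 ± 0.03, Cd69 by 0.37 ± 0.03 and Bcl2 by 0.25 ± 0.03. All 25 G2/M genes and 27 of 29 S phase genes rose (25 and 28 adjusted over the list alone), with camera adjusted p of 8.37e-25 and 1.94e-15 and, with an estimated correlation, adjusted p of 0.0990 and 0.200. Cholesterol biosynthesis had 14 of 17 higher, oxidative phosphorylation 17 of 34 higher and 1 lower, glycolysis 10 of 17 higher and 2 lower, and type I interferon 12 of 24 higher and 1 lower. Their camera adjusted p was 1.10e-06, 7.98e-05, 0.00707 and 7.98e-05, and the adjusted p with an estimated correlation was 0.112, 0.200, 0.200 and 0.571. Early activation had 14 of 25 lower and 1 higher (2 with the block) and the naive list 12 of 24 lower and 1 higher, with camera adjusted p of 0.000413 and 0.00324 and, with an estimated correlation, adjusted p of 0.0990 and 0.200.

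Il7r had a slope of 0.07 ± 0.05 (adjusted p 0.28) and Cd4 one of 0.02 ± 0.02 (adjusted p 0.60). Of the other-cell markers, Cd86 fell by 0.65 ± 0.04 and Cd72 by 0.42 ± 0.05 per division, and H2-Ab1 rose by 0.26 ± 0.03 and Klrd1 by 0.30 ± 0.05. By list, 2 of 10 B cell genes rose (4 with the block) and 2 fell, 1 and 1 of 4 plasma cell genes, 2 and 1 of 8 myeloid genes, 0 and 1 of 1 CD8 T cell gene and 0 and 1 of 6 dendritic cell genes. Hbb-bt (-0.21 ± 0.10, adjusted p 0.106), Hba-a1 (-0.17 ± 0.10, 0.17) and Pecam1 (-0.07 ± 0.03, 0.073) passed only with the block (0.011, 0.042 and 0.0036). The trend called 1844 rising and 1959 falling genes (3803 of 9566). With median centring these were 1033 and 1725, and with every probe tested 6356 probes passed.

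**Figure D3:**
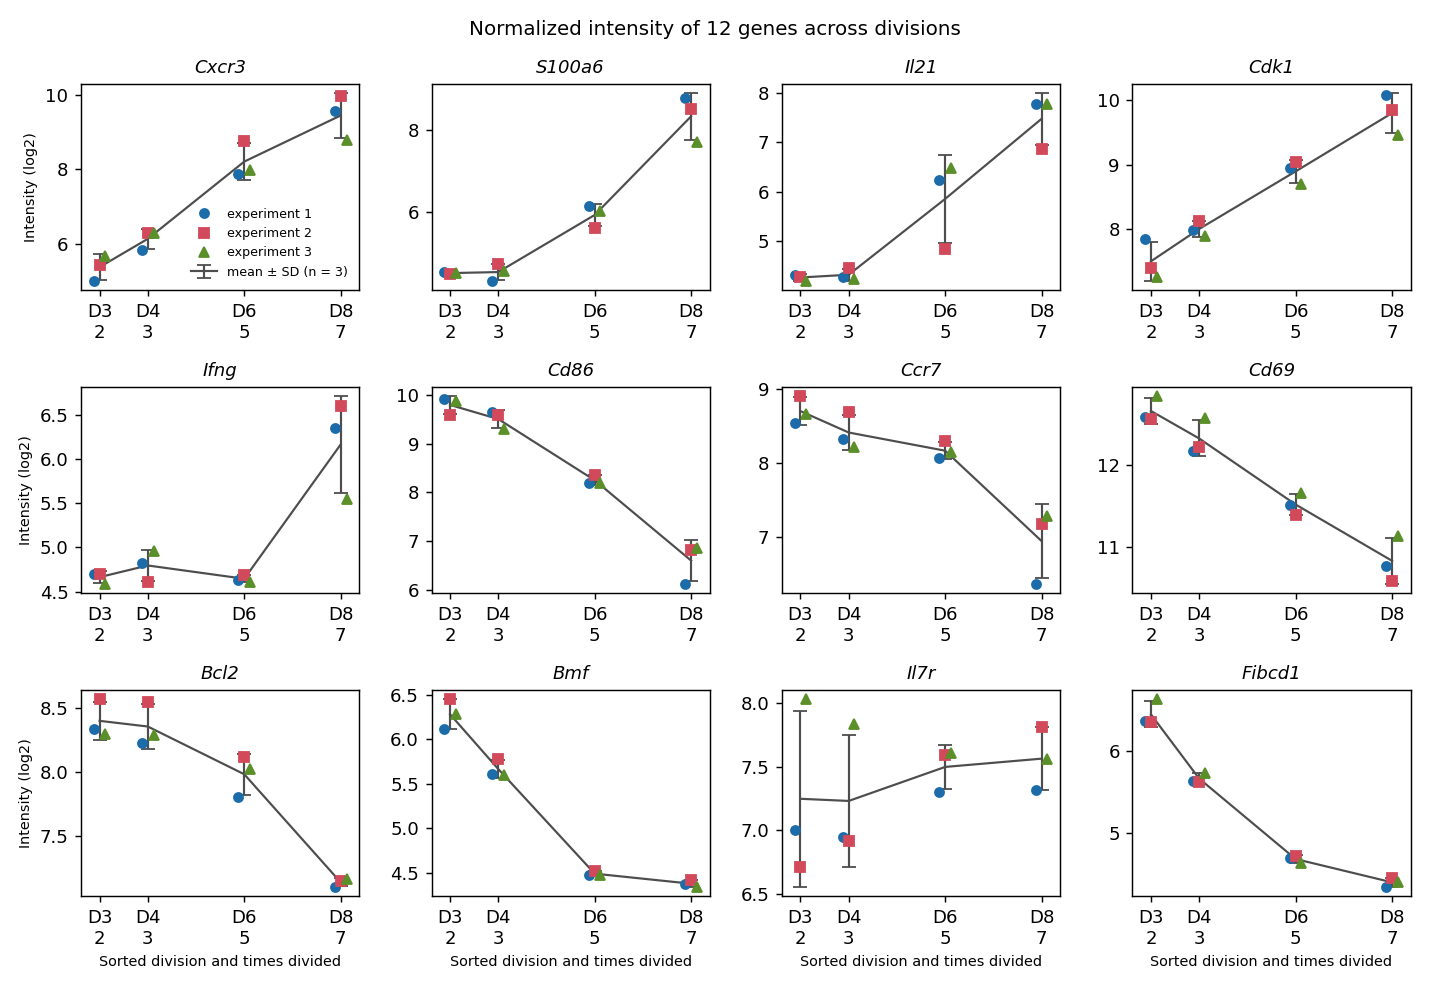
Normalized intensity (log2) of 12 genes on each of the 12 arrays against sorted division and times divided, with points coloured by experiment and lines joining the mean and SD of each division (n = 3). Cxcr3 means rise from 5.37 in D3 to 9.44 in D8, Cd86 means fall from 9.79 to 6.61, and Il7r means lie between 7.23 and 7.56.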

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

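The numbers of genes called depended on the model and on the normalization. With the experiment as a block the counts were 65 for D4 against D3, 949 for D6 against D4, 2214 for D6 against D3, 1662 for D8 against D6 and 1209 for D4 against the mean. With median centring they were 162 for D6 against D4, 1594 for D8 against D4, 930 for D6 against D3, 338 for D8 against D6 and 226 for D4 against the mean, and the share of called genes that were higher went from 49.9% to 24.7% for D6 against D3, from 48.2% to 36.8% for D8 against D3 and from 48.5% to 37.5% for the trend. With every detected probe tested, 4271 probes were called for D8 against D4, 2162 for D6 against D3, 5740 for D8 against D3 and 6356 for the trend. D4 against D3 gave 9 genes with the authors' values and 0 with normexp and offset 50, with no background correction, with every probe tested, with trend and robust, and with only the arrays of its 2 divisions. Without 1 array at a time the counts ranged over 0 to 2 for D4 against D3, 215 to 465 for D6 against D4, 2015 to 2733 for D8 against D4, 938 to 1455 for D6 against D3, 2755 to 3505 for D8 against D3, 370 to 1047 for D8 against D6, 281 to 726 for D4 against the mean, 0 to 0 for genes apart at D4 and 3193 to 3771 for the trend. Called comparisons of genes that the rule for named genes took, not all of them named in the text, numbered 664. Of these, 117 lost the call with median centring, 76 with the authors' values, 69 with no filter and 9 with trend and robust. The call was lost in 8 with normexp, 4 with no background correction, 4 with array weights, 0 with the block and 20 to 58 without 1 array. None of these settings turned the direction of any of these comparisons. Among all called genes, some did not keep their sign with the authors' values. These were 31 of 2728 for D8 against D4, 29 of 3492 for D8 against D3 and 21 of 3803 for the trend. With these floored values the median change of all genes was 0 for D8 against D4 and for D8 against D3. Genes that the floor made constant may be among those counted, so the counts do not show that directions reversed. Of 61 camera calls in 248 tests, 61 were lost with an estimated correlation, 12 with fry, 3 with median centring and 1 with the block, while 54 further lists passed with fry, 18 with no filter, 7 with median centring, 7 with no background correction and 6 with the block. A test with an estimated correlation found a simulated 1.5-fold shift of 25 genes (adjusted p 4.56e-06) and called 0 of 30 lists without a shift. The simulated members were drawn at random with noise independent between genes. The simulation therefore cannot show that this test finds shifts in lists whose members vary together. The correlation was not estimated with the block, so the 61 losses may come in part from the experiment left out of the model. The inhibitory receptors, D8 against D3, were upward with fry (adjusted p 0.0158) and downward with camera (0.990), with a median of -0.34 and a mean of 0.22. A term for the slide was not run, since no slides are named.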

Other observations

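Of 31 families of genes taken by symbol, 7 passed a Fisher test (adjusted p under 0.05) for a larger share of genes rising with division. Of all genes 19.3% rose. Some members of the families are counted in the fixed lists as well. The families, their members named here and their tests were chosen after the values were seen, outside the rule for named genes, and p was adjusted over their 62 tests for rising and falling members with the trend. Of 47 replication-dependent histone genes, which package new DNA, 31 rose and 1 fell (adjusted p 2.01e-10): H2ac11 rose from D3 to D8 by 2.45 ± 0.15, H2ac21 by 2.58 ± 0.18 and H2ac12 by 2.30 ± 0.16, and H2ac18 fell by 0.93 ± 0.16. Probes for near-identical histone copies can share signal. Of 8 Mcm genes, nearly all of which are in the S phase list, 7 rose (adjusted p 0.00135). Of 22 kinesins, motors along microtubules, 12 rose and 4 fell (adjusted p 0.00370), Kif11 and Kif22 of the G2/M list belonging to them, with Kif2c at 2.50 ± 0.15, and Kif13b fell by 0.65 ± 0.16. Of 10 tubulins 6 rose and 1 fell (adjusted p 0.0361), with Tubb2b at 3.13 ± 0.23 and Tubb6 at 1.37 ± 0.22, and Tubb4a fell by 0.56 ± 0.12.

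Proteasome subunits, which degrade tagged proteins, had 18 of 34 genes higher and 0 lower (adjusted p 0.000358), with Psmc3 at 0.83 ± 0.13 and Psmd13 at 0.73 ± 0.10, and 6 of them higher with median centring. S100 proteins, annexins and galectins together had 10 of 19 higher and 2 lower (adjusted p 0.0103), and S100 proteins alone 5 of 7 higher (adjusted p 0.0304), so these 2 passing families overlap. Annexins alone (2 of 6 higher, adjusted p 0.650) and galectins alone (3 of 6 higher, 2 lower, 0.306) did not pass. S100a6, Anxa2 and Lgals1 are also in the Th1 list. Chemokine receptors (5 of 9 higher but 3 with the authors' values, 2 lower, adjusted p 0.0797), dual-specificity phosphatases (8 of 16 lower, 1 higher but 0 under the other 4 scalings, 0.0501), TNF receptors (7 of 14 lower, 1 higher, 0.0681) and MHC class II genes (5 of 8 lower, 1 higher, 0.0649) did not pass. These Fisher tests treat genes as independent, which genes of 1 array are not. The directions of the 7 families that passed held under all 5 scalings.

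The tests of host T cells, of antigen-presenting cells and of the distance of D4 in the next 3 paragraphs were chosen after the results were seen. S phase and G2/M genes rose from D3 to D8, and of the 53 that did, 53 stayed called with the median intensity of each array as a covariate. That intensity was 48.8 ± 2.79 (SD, n = 3) in D3 and 47.5 ± 5.11 in D8. These means lay within their spread, so the covariate could take up little of the change. The count of 53 therefore decides little about array brightness, whereas the similar medians argue against it as the whole cause. Dividing host T cells without dye may have entered the D8 gate, but the median G2/M change was 1.47 ± 0.13 (SD, n = 3 experiments) from D3 to D6, which argues against them as the whole cause. A part in the rise from D6 to D8 stays open: from D3 to D8 Cd4 changed by 0.0906 ± 0.18 (SD, n = 3 experiments), which such cells would share, and the labels name no gate on the transferred receptor. Division number, which the design names, stays an untested biological explanation.

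Cd86, Cd83, Cd72, H2-Oa and H2-DMb2 fell together from D3 to D8, with a median of -2.05 ± 0.44 (SD, n = 3 experiments), and H2-Oa was named outside the rule. Antigen-presenting cells in the early gates could bring them, and would bring Cd74, H2-Ab1, H2-Eb1, Cst3 and Cd79b too. The median of those 5 changed by 0.450 ± 0.29 (0.45, 0.16 and 0.74 in experiments 1, 2 and 3), the other way, although Ctss fell by 0.81 ± 0.18, Cd79b had -0.26 ± 0.29, and 5 of 8 class II and loading genes fell with the trend. The values of the 5, with Cd74 at a log2 intensity of 6.22 in D3 and 6.97 in D8 and Cst3 at 9.83 and 9.90, argue against such cells as the source of the whole fall, and a part in it stays open. A change within the T cells is a hypothesis that was not tested on other data.

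No gene was apart at D4 from D3, D6 and D8 together: limma called 0, with 21 at an unadjusted p under 0.05. A lack of arrays could hide large changes, but 0 genes had a D4 mean 2-fold or more beyond all 3 other means and 0 had one 1.5-fold or more beyond, whatever their p. The nearest were Cxcr4 (0.56 log2 units below), Taf6 (0.47 below) and Pim2 (0.47 above), of which Taf6 was named outside the rule. These are observed means of 3 arrays and carry error: D4 minus D3 of Cxcr4 was -0.60 ± 0.30. The counts therefore do not exclude true 1.5-fold changes, of which the simulation recovered 43.3% with 200 genes changed. Where few genes differ, that share can be lower. Changes of about 1.5-fold and smaller ones stay open. A single axis of expression was predicted to give a correlation of D4 minus D3 with D8 minus D6 above 0.1 with a permutation p under 0.05: the correlation was 0.271 with an exact permutation p of 0.14 over 400 assignments, so the prediction was missed, but a p that misses excludes nothing, and the 64 assignments that part the pairs cannot give a p below 0.0625, which is what they gave. Departure of D4 from the line between D3 and D6 was predicted to show in at least 10 genes and limma called 0 with and without the block, so that prediction was missed as well, but a count under that bound excludes no departure here: at an unadjusted p under 0.05 there were 306 genes without the block and 579 with it, where uniform p give 478, and D4 against D3 called 1 gene in the same arrays that called 1419 between D3 and D6.

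Other assignments of the arrays were compared with the real one, without regard to the experiment that pairs them. For each pair of divisions the 10 splits of 6 arrays are too few for a share under 0.05: 1 split of 10, the real one, gave as many genes (1, 408, 2728, 1419, 3492 and 891 for D4 against D3, D6 against D4, D8 against D4, D6 against D3, D8 against D3 and D8 against D6), and the highest other gave 0. Each other split mixes both divisions on each side, so a real difference adds to the spread and lowers its count. The 0 is therefore not a level that chance alone would give. For D4 against the mean, 2 of 100 assignments gave 566 genes or more, the highest other 1147, which put 2 D8 arrays and 1 D6 array in the place of D4, a structure of the samples along division. For the trend 1 of 100 gave as many as 3803, the highest other 1675. For genes apart at D4 at an unadjusted p under 0.05, 46 of 100 assignments gave 21 or more, the highest other 909. That assignment also put 2 D8 arrays and 1 D6 array in the place of D4, so the other assignments carry the structure along division. Chance is not excluded, but arrays of 1 experiment correlate and the block gave 47 genes in place of 21.

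Of 2857 detected probes without a single symbol, 804 were called between D8 and D3, 551 between D8 and D4 and 0 between D4 and D3 with limma. S1pr1, Eomes, Gzmb and Prdm1 had probes but none detected on at least 3 arrays, and Tcf7 and Mki67 had no named probe, so these genes were not analysed here.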
